A study of Caldicellulosiruptor acetigenus and Caldicellulosiruptor saccharolyticus and Caldicellulosiruptor bescii and Caldicellulosiruptor hydrothermalis with 6 samples.

How the data were processed

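Genomic DNA of 6 tester species, 1 sample each, was compared with C. saccharolyticus DNA on 12 two-colour arrays, 2 per species with the dyes exchanged. Per the labels' protocols, DNA was partially digested with Hae III, labelled by incorporating amino allyl-dUTP with Klenow fragment and random nonamers, and coupled to Cy3 or Cy5. The authors deposited scanner tables whose values are spot intensities per channel, per the file headers: median and mean pixel intensity, local background with its SD, background-subtracted intensity and a flag per spot. The authors also deposited a table of log2 values per gene and species for 2679 genes; how it was normalized is not given in the sources used here. Set against the scanner values, its columns correlated with the ratios computed here at 0.98 in C. bescii, 0.89 in C. hydrothermalis, 0.99 in C. kristjanssonii, 0.85 in C. kronotskyensis, 0.98 in C. lactoaceticus and 0.99 in C. owensensis, so it runs in the same direction. Its column medians were -0.01, -0.01, -0.12, 0.01, -0.01 and -0.16 in that order; its centring stays unknown, and it served as an alternative.

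Each array had 15552 spots. Spots with flag 3 were used, a code whose meaning the files do not state; between 0.26% and 15.1% of gene spots were left out per array, most on an array of C. hydrothermalis. The number of arrays limits the precision, and each species had 1 sample.

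The dye of the tester on each array was read from the deposited name of that array, and channel 1 was taken as Cy3 and channel 2 as Cy5, which is the usual convention and is not stated by the labels. The ratio of channel 2 to channel 1 ran in opposite directions on the 2 arrays of every species (Spearman correlation across genes from -0.14 in C. hydrothermalis to -0.89 in C. owensensis), so the channels follow the dyes. Under that assignment, empty spots were a larger share of the median gene signal in the tester channel than in the reference channel on 12 of 12 arrays, as a tester less matched to the probes gives. Arrays of 1 dye orientation correlated between species at -0.01 to 0.60. Exchanging the channels would turn the sign on both arrays, so these correlations do not bear on the direction. Against the assignment, the channels taken as the common reference correlated less between species (mean Spearman correlation 0.358) than those taken as the testers (0.414), where a shared reference would be thought to correlate more. The direction is therefore called likely and no more, and every reduced or elevated call rests on it.

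For each array, background-subtracted median intensities were used, the tester channel was scaled so that the median log2 ratio was 0, both channels were floored at the higher of the channels' limits (2 times the median background SD, after scaling, and at least 1), and the log2 ratio of tester over reference was taken as the median over the spots of a probe and then the mean of the 2 orientations. A gene lacking a usable spot in either orientation was left out for that species. Because each array was centred on its median gene, a ratio shows only unequal hybridisation relative to that gene. No loess or quantile step was part of the main setting, since many genes of a diverged species can shift one way. Empty spots had signal above their local background, from 10.5% to 75.0% of the gene median in the tester channel and from 0% to 60.5% in the reference channel. A gene was counted in range for a reduced call where a tester signal equal to the median of the empty spots would have given -1 or lower on both arrays. The tester signal of a gene counted as at the level of empty spots when it was at or below their 95th percentile on both arrays, with the reference above it on both. An at-least fold sets the reference signal against the higher of that percentile and the tester signal, as the mean over both arrays.

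Calls per species follow fixed sizes with no p-value. The mean over species and the contrast of the C. acetigenus-labelled pair were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg over all genes). Gene lists were compared with 10000 random lists of the same size matched on reference signal in 20 bins, and runs with 1000 shuffles of gene order. The tests, sizes, lists and most alternatives were chosen before the data were examined. Tested on simulated data for 2695 genes, with 200 genes changed, the limma mean recovered 43.0% of genes set to -1, 90.5% at -1.5 and 98.0% at -2. In the same order it also called 5, 15 and 18 unchanged genes. These figures count limma's adjusted p under 0.05 at any size. They do not cover calls that also need a mean of -1 or lower.

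Of 20 gene lists fixed beforehand, 18 were defined by product name. The array files and the authors' table give no product names and no annotation was used here, so those 18 matched no member and are not analysed here; 2 lists by locus tag were used. The rule for named genes was written as follows: for the mean over species the lowest and highest genes with adjusted p under 0.05 the same sign in every species measured and, for the lowest, tester signal above the empty spots in at least 1 species; for each species the lowest genes reduced there and retained in at least 4 of the others, and the highest genes retained there and reduced in at least 4 of the others; for the pair the largest changes; and every member of both locus lists. It allowed more genes than are printed: without names, at most 2 genes per direction and comparison are printed beside the locus lists and the ends of runs. Alternatives covered background correction, pixel summary, centring, loess, a filter on dim reference probes, flagged spots, single orientations, the authors' table, sizes and call rule, the eBayes settings, species left out and the range of array numbers as a block. Subtraction of the empty spots, detection against them, blocks of as many neighbouring genes (with at least 3 measured) in place of random lists, and leaving out C. hydrothermalis and C. kronotskyensis together were chosen after seeing the data.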

Results

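The series compared the genomic DNA of 6 Caldicellulosiruptor species, extremely thermophilic and plant biomass-degrading bacteria, with that of a seventh, C. saccharolyticus DSM 8903. The testers were C. bescii DSM 6725, C. hydrothermalis DSM 18901, C. kristjanssonii DSM 12137, C. kronotskyensis DSM 18902, C. lactoaceticus DSM 9545 and C. owensensis DSM 13100, all grown at 70 °C in 500 mL cultures. Each tester was hybridised together with the C. saccharolyticus reference on an array of C. saccharolyticus genes, on 2 arrays with the dyes exchanged. The 2 arrays of a species are a technical dye swap of 1 DNA sample, so each species counts as 1 sample and differences between single species have no replicate check. The array held 2695 C. saccharolyticus gene probes with 5 spots each, 98 other probes and 1587 empty spots. A log2 ratio of tester over reference is given relative to the median gene of its array: a negative value means weaker hybridisation of the tester than at the median gene, as lost or diverged sequence gives, and a positive value stronger hybridisation. The direction is likely rather than stated, because the labels name the dyes but not the scanner channel that holds each; its basis is given with the processing. The files do not pair the locus tags with gene names, so genes appear by tag.

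The first question was how much of the C. saccharolyticus gene set each species hybridised less strongly. With reduced meaning a log2 ratio of -1 or lower in both orientations, C. lactoaceticus had 406 reduced genes of 2693 measured (15.1%), C. owensensis 356 of 2695 (13.2%), C. bescii 257 of 2671 (9.62%), C. kristjanssonii 208 of 2695 (7.72%), C. hydrothermalis 89 of 2523 (3.53%) and C. kronotskyensis 57 of 2616 (2.18%). The order of the species changed with the processing: loess gave 147 in C. lactoaceticus, below C. owensensis (399), C. bescii (240) and C. kristjanssonii (205), and centring on the mode gave C. bescii the highest count (238). The authors' table, with 1 value per gene and species and so no rule on both orientations, gave 358 in C. kronotskyensis and 302 in C. bescii. Genes at -2 or lower in both orientations numbered 51 in C. lactoaceticus, 56 in C. owensensis, 23 in C. bescii, 28 in C. kristjanssonii, 3 in C. hydrothermalis and 5 in C. kronotskyensis. Genes with a mean ratio above -0.5, called retained, made up between 65.2% of those measured in C. lactoaceticus and 80.1% in C. kronotskyensis. With the ratio turned, genes below 0.5 made up between 61.8% in C. lactoaceticus and 77.4% in C. hydrothermalis. Centring on the median gene puts most genes above -0.5 whatever the divergence, so these are not shares of conserved genes. They also depend on the spread: the SD across genes was 1.26 in C. lactoaceticus and 0.75 in C. kronotskyensis. Genes at 1 or higher in both orientations were most numerous in C. owensensis (600), C. kristjanssonii (479) and C. lactoaceticus (441), with 98 in C. bescii, 92 in C. kronotskyensis and 9 in C. hydrothermalis. Were the direction the opposite, these would be the reduced genes. A positive ratio does not ensure tester signal above the empty spots. In C. lactoaceticus, Csac_2411 had a mean of 1.79 with tester signal at their level. Genes at 1 or higher with such signal were not counted.

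These counts cannot be ranked as shares of lost genes, because the arrays differed in range. Empty spots carried tester signal, and a gene was counted as in range where a tester signal at their median would itself have given -1 or lower on both arrays. That held for 1996 genes in C. kristjanssonii, 1967 in C. owensensis, 1149 in C. bescii, 863 in C. lactoaceticus, 594 in C. kronotskyensis and 505 in C. hydrothermalis. Among those genes the reduced share was 17.7% in C. bescii, 7.33% in C. hydrothermalis, 10.4% in C. kristjanssonii, 4.55% in C. kronotskyensis, 42.9% in C. lactoaceticus and 17.3% in C. owensensis. With the ratio turned, and the range set by the reference signal of empty spots, the shares in the same order would be 3.88%, 0.697%, 17.8%, 8.02%, 16.4% and 22.3%, so the order of the species rests on the likely direction. Reduced genes outside the range for a reduced call numbered 52 of 89 in C. hydrothermalis, 30 of 57 in C. kronotskyensis, 54 of 257 in C. bescii, 36 of 406 in C. lactoaceticus, 16 of 356 in C. owensensis and 0 in C. kristjanssonii. This too rests on the likely direction. With the ratio turned, 8 of 9 genes would lie inside the turned range in C. hydrothermalis, 86 of 92 in C. kronotskyensis and all in the other species. The correlation across genes between the 2 orientations was 0.90 in C. owensensis, 0.72 in C. lactoaceticus, 0.72 in C. bescii, 0.68 in C. kristjanssonii, 0.44 in C. kronotskyensis and 0.07 in C. hydrothermalis. In simulated arrays with the orientation spread of C. hydrothermalis, 46 unchanged genes were called reduced beside 200 genes set to -2, a number to hold against its 89 reduced genes; it was 13 at the spread of C. lactoaceticus and 0 at that of C. owensensis.

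**Figure D1:**
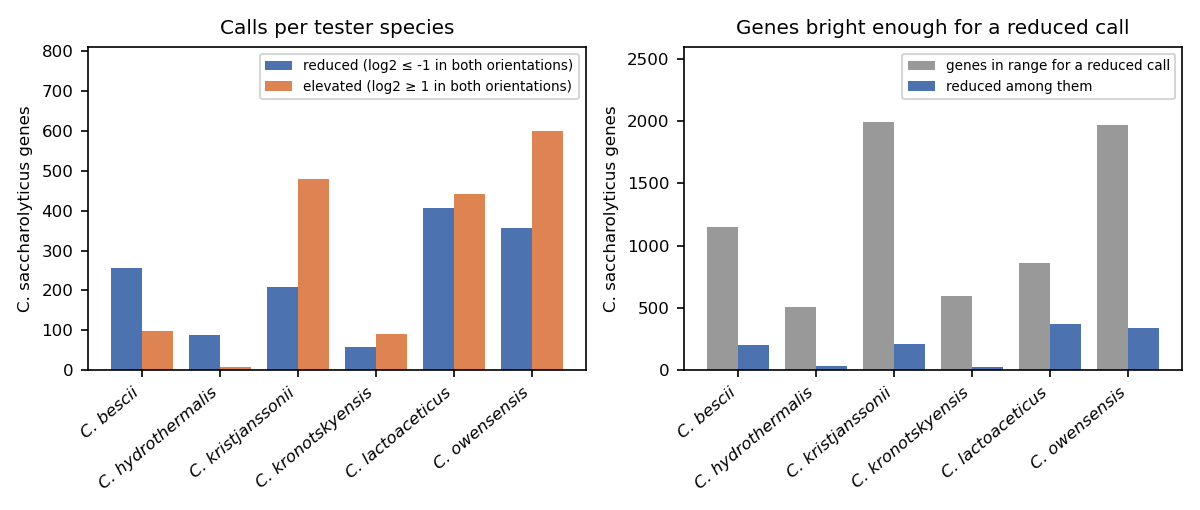
Left, number of C. saccharolyticus genes called reduced (log2 ratio of -1 or lower in both orientations) and elevated (1 or higher in both) in each tester species; right, genes whose reference signal left room for a reduced call on both arrays, and the reduced genes among them. C. kristjanssonii and C. owensensis had 1996 and 1967 genes in range, and C. hydrothermalis 505.

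By the scanner's own local background, no gene of any species had a tester signal below background on both arrays while the reference passed. In C. bescii the median background SD was 0 in both channels of both arrays, so this limit was hardly one there. Without background subtraction its count of reduced genes was again 257, so that alternative checks little in C. bescii. The 95th percentile of the empty spots gave other counts. The tester signal was at or below that level on both arrays, with the reference above it on both, for 356 genes in C. lactoaceticus and 215 in C. kronotskyensis. There were 126 such genes in C. bescii, 43 in C. owensensis, 30 in C. hydrothermalis and 25 in C. kristjanssonii. Among the reduced genes, 46 were at that level in C. lactoaceticus, 34 in C. bescii, 33 in C. kronotskyensis, 19 in C. owensensis, 14 in C. kristjanssonii and 6 in C. hydrothermalis. For such genes a ratio is a limit, written as at least N-fold, and gives no order among them. Genes at that level on 1 array only are outside these counts, and their ratios are printed as measured. On the Cy5 array of C. hydrothermalis the 95th percentile was 1220 beside a tester gene median of 883. On that of C. kronotskyensis it was 526 beside 329.

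Some genes were reduced in a species and retained in at least 4 of the other 5, which leaves room for 1 more species with a low ratio. There were 77 such genes in C. lactoaceticus, 66 in C. owensensis, 32 in C. kristjanssonii, 31 in C. hydrothermalis, 14 in C. bescii and 3 in C. kronotskyensis. These numbers rest on the likely direction, and this class was not counted with the ratio turned. The fixed rule took the lowest ratios, which have no order among genes with tester signal at the level of empty spots. In C. lactoaceticus it named Csac_1639 and Csac_1636, both at that level and at least 3.83-fold and at least 3.57-fold lower in the tester; both were also reduced in C. owensensis, at -2.61 and -1.67. In C. owensensis, Csac_0442 had a ratio of -3.17 (orientations 0.273 to either side), against a mean of -0.10 in the other 5 species (SD 0.43), and Csac_1651 had -2.66 (0.454 to either side), with -1.40 in C. lactoaceticus. In C. kristjanssonii, Csac_1060 had -2.56 against 0.17 in the others (SD 0.73), and Csac_0811, with tester signal at empty-spot level, was at least 5.34-fold lower. In C. hydrothermalis the rule named Csac_2726, at least 2.44-fold lower, and Csac_1079 at -3.42, whose orientations lay 1.55 to either side of that mean. In C. bescii it named Csac_0401, at least 3.68-fold lower and also reduced in C. owensensis (-2.22), and Csac_1557, whose bound of at least 1.15-fold does not reach a 2-fold reduction. In C. kronotskyensis it named Csac_2642 at -1.46, with -1.41 in C. kristjanssonii, and Csac_0627 at -1.43. Neither kept a mean of -1 or lower with mean pixel signal (-0.52 and -0.89) or with the empty spots subtracted (-0.59 and -0.72).

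The opposite class, retained in a species and reduced in at least 4 of the other 5, held 22 genes in C. hydrothermalis, 22 in C. kronotskyensis, 5 in C. bescii, 2 in C. owensensis and 0 in C. kristjanssonii and C. lactoaceticus. C. hydrothermalis and C. kronotskyensis also had the fewest genes in range for a reduced call (505 and 594), and a gene can count as retained for lack of range. C. bescii and C. kronotskyensis shared the leading genes of this class. Csac_1080 had a ratio of 1.11 in C. bescii (orientations 1.70 and 0.515) and 1.32 in C. kronotskyensis (1.43 and 1.21). Csac_1064 had 0.68 in C. bescii, where 1 orientation gave 1.37 and the other -0.0038. In the single orientations of C. kronotskyensis it had 1.26 and 1.74. The 2 genes of this class in C. owensensis were Csac_2571 at 0.93 and Csac_2532 at 0.92, the latter against a mean of -2.16 in the other species (SD 0.79), but with loess they were at -0.26 and -0.24. The leading genes in C. hydrothermalis were Csac_2542 at 1.71 and Csac_0263 at 1.57. Their reference signal was at the level of empty spots on at least 1 array. With the median of the empty spots subtracted, which also raised the floor, their ratios were 0.00 and 0.15. Spots under the floor in both channels have a ratio of 0, so the 0.00 cannot be read as equal signal.

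Across the genus, the comparison asked which C. saccharolyticus genes were weaker or stronger in the 6 testers as a set. The mean ratio over the 6 species was tested against 0 with limma, species being the units; this leaves out the spread of the reference DNA itself. Of 2695 genes, 196 were lower (adjusted p under 0.05 and a mean of -1 or lower) and 350 higher (1 or higher), and 754 passed at any size, 307 below and 447 above 0. The lowest were Csac_2531 with -2.65 ± 0.76 (SD, n = 6; limma adjusted p = 0.000815) and Csac_1104 with -2.29 ± 0.71 (SD, n = 6; limma adjusted p = 0.00119), both below 0 in 6 of 6 species. The highest were Csac_2502 with 2.19 ± 0.89 (SD, n = 6; limma adjusted p = 0.00185) and Csac_0361 with 2.17 ± 0.81 (SD, n = 6; limma adjusted p = 0.00185), both above 0 in 6 of 6. Neither Csac_2502 nor Csac_0361 had tester signal at the level of empty spots in any species. Such signal was not counted over the 350 higher genes. Without C. hydrothermalis and C. kronotskyensis, whose orientations agreed least, 312 genes were lower.

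Counted by species, 1754 of the 2439 genes measured in all 6 species were reduced in none (71.9%), 384 in 1, 153 in 2, 93 in 3, 39 in 4, 15 in 5 and 1 in all 6. Independent lists of the same sizes would give 803 genes in 1 species, 172 in 2, 18.0 in 3, 0.954 in 4 and 0.0239 in 5, so that more genes than this were reduced in 3 or more species and fewer in 1 or 2. With the ratio turned, the numbers of genes in 0 to 6 species would be 1501, 479, 269, 153, 34, 2 and 1. The single gene reduced in all 6, Csac_2725, is named because it is the only one; its tester signal was at the level of empty spots in 4 species, so no size is given. Without C. hydrothermalis 10 genes were reduced in all others, without C. kronotskyensis 5, and without both 45 genes were reduced in all of the remaining 4. Only 149 genes were in range for a reduced call in all 6 species, so most of the 1754 were out of range in at least 1. Of 626 genes in range in C. bescii, C. kristjanssonii, C. lactoaceticus and C. owensensis, 293 were reduced in none of these species.

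Plant polysaccharide degradation was represented by 2 runs of neighbouring genes fixed by locus tag before the data were examined. The CelA locus list, Csac_1076 to Csac_1081, takes its name from a multi-domain cellulase known from C. saccharolyticus, and the xylan locus list, Csac_2404 to Csac_2411, from xylan degradation. The median ratio of the CelA locus was 0.73 in C. bescii and 0.42 in C. kronotskyensis, at percentiles 93.5 and 82.2 of random lists of the same size and reference signal. It was -0.93 in C. kristjanssonii, -0.72 in C. lactoaceticus, -1.23 in C. owensensis and -2.72 in C. hydrothermalis, at percentiles 1.17, 6.19, 0.16 and 0. Neighbouring genes had similar ratios, so lists of scattered genes make a block of neighbours look rarer than it is. Among blocks of as many neighbouring genes, a comparison added after seeing the data, the percentiles were 84.9 in C. bescii, 78.9 in C. kronotskyensis, 9.71 in C. kristjanssonii, 16.4 in C. lactoaceticus, 5.56 in C. owensensis and 0 in C. hydrothermalis. With only genes whose reference signal passed on every array, the C. lactoaceticus median turned to 0.26. That of C. hydrothermalis lay between -2.83, centred on the mode, and -1.13, in the authors' table. As reported it rests on 4 measured members, of which Csac_1077 and Csac_1079 had orientations 1.10 and 1.55 to either side. The C. owensensis median lay between -2.28, with the empty spots subtracted, and -0.80, with the filter on reference signal. Reduced members numbered 3 of 6 in C. owensensis, 3 of 4 measured in C. hydrothermalis, 2 in C. kristjanssonii, 1 in C. lactoaceticus and 0 in C. bescii and C. kronotskyensis. Csac_1080 had ratios of 1.11 in C. bescii and 1.32 in C. kronotskyensis, and of -1.28 in C. kristjanssonii, -2.46 in C. hydrothermalis and -3.13 in C. owensensis; in C. lactoaceticus it was reduced with tester signal at the level of empty spots. Csac_1076 had 1.13 in C. bescii and -3.22 in C. owensensis, with the orientations 0.052 and 0.148 to either side. Over the 6 species 1 of the 6 members passed, Csac_1081 with a mean of -1.15 ± 0.43 (SD, n = 4; limma adjusted p = 0.0205), where the C. owensensis value was at the level of empty spots; adjusted over the list alone it was again 1 of 6. The call for Csac_1081 did not hold without C. kristjanssonii (-1.09) or without C. owensensis (-0.98). The differences between species in this list were not tested, each species having 1 sample.

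The xylan locus was lowest in C. kristjanssonii, with a median of -1.61 and 5 of 8 members reduced (percentile 0). The median was -1.10 in C. hydrothermalis (percentile 0.06, 2 of 6 measured members reduced), but -0.62 in the authors' table and -1.72 on the Cy5 array alone. It was -0.84 in C. bescii (percentile 0.77, 3 of 8), and there -0.49 with flagged spots kept, -0.45 with the filter on dim reference probes and -0.17 in the authors' table. The medians were -0.05 in C. kronotskyensis, -0.06 in C. owensensis and 0.20 in C. lactoaceticus, at percentiles 34.2, 28.8 and 27.9. Among blocks of neighbouring genes the percentiles were 1.95 in C. kristjanssonii, 3.67 in C. hydrothermalis, 10.3 in C. bescii, 43.5 in C. kronotskyensis, 46.5 in C. owensensis and 57.9 in C. lactoaceticus. In C. lactoaceticus 5 of the 8 members had tester signal at the level of empty spots, and its median turned to -0.89 with the empty spots subtracted, -0.72 with normexp and -0.62 with loess. Over the 6 species 2 of 8 members were lower, Csac_2405 with -1.47 ± 0.75 (SD, n = 5; limma adjusted p = 0.0057) and Csac_2407 with -1.33 ± 0.41 (SD, n = 5; limma adjusted p = 0.0052), the latter at the level of empty spots in 3 species; the same count passed adjusted over the list alone. Csac_2410 was above 0 in every species but C. hydrothermalis (-0.59), with ratios from 0.32 to 0.81.

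**Figure D2:**
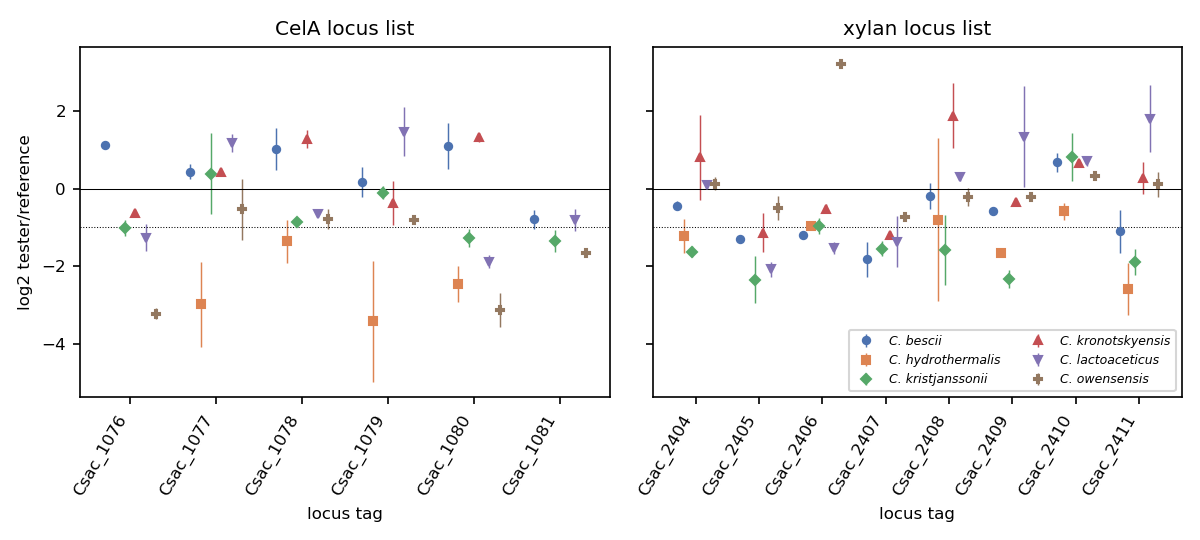
Log2 ratio of tester over reference for each member of the CelA locus list (left) and the xylan locus list (right) in the 6 tester species; points are means of the 2 dye orientations, bars reach to the single orientations, and the dotted line marks -1. At Csac_1080, C. bescii (1.11) and C. kronotskyensis (1.32) lie above 0 and the other species below -1.

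The labels place 2 testers together: C. kristjanssonii and C. lactoaceticus are both given the organism name C. acetigenus. No gene of 2695 passed limma's adjusted p under 0.05 between these 2 species and the other 4, where 188 had an unadjusted p under 0.05 (72 lower and 116 higher in the pair); eBayes with trend and robust settings called 3. By their running numbers the arrays of C. hydrothermalis and of C. kronotskyensis lay in ranges apart from each other and from those of the other 4 species. Within those 4 species no gene passed limma's adjusted p under 0.05, and 147 of 2694 had an unadjusted p under 0.05. With the range as a block the numbers were 0 and 137 of 2439. The block fits C. hydrothermalis and C. kronotskyensis exactly, each being alone in its range. It therefore compares the same 4 species and is no separate check. The farthest apart were Csac_2605, with a mean of 3.01 in the pair and -0.37 in the others (limma adjusted p = 0.0847), and Csac_0886, with -2.16 in the pair and 1.86 in the others (limma adjusted p = 0.0847). With 2 against 4 species the test was weak: of 200 simulated genes set 2 apart on the log2 scale 7.5% were recovered, and 85.5% at 3.

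Similarity of whole profiles was described by correlation across genes, which are not independent replicates, so no p-value is given. Each array carried its own reference hybridisation. The ratios of C. kristjanssonii and C. lactoaceticus correlated at 0.61 (Spearman 0.61), second of the 15 species pairs after C. bescii and C. kristjanssonii at 0.62. Its rank was 1 under 7 of the 12 settings run, 2 under 3, 3 without background subtraction and 6 on the Cy3 arrays alone. The lowest was C. bescii with C. hydrothermalis at 0.21. The C. acetigenus-labelled pair shared 91 reduced genes, where independent lists would share 31.4, and ranked 6 of 15 by the share of their reduced genes held in common; C. lactoaceticus and C. owensensis shared 174, where they would share 53.7. Every pair shared more than independent lists would, by 1.66 to 4.97 times, and by 1.63 to 9.22 times with the ratio turned. The reference DNA was common to all pairs, and independent lists leave out what it contributes to the sharing. The rank rests on the likely direction: with the ratio turned, the C. acetigenus-labelled pair would share 246 genes, where independent lists would share 78.4, and rank 1. C. lactoaceticus and C. owensensis would then share 226, where independent lists would share 98.1.

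**Figure D3:**
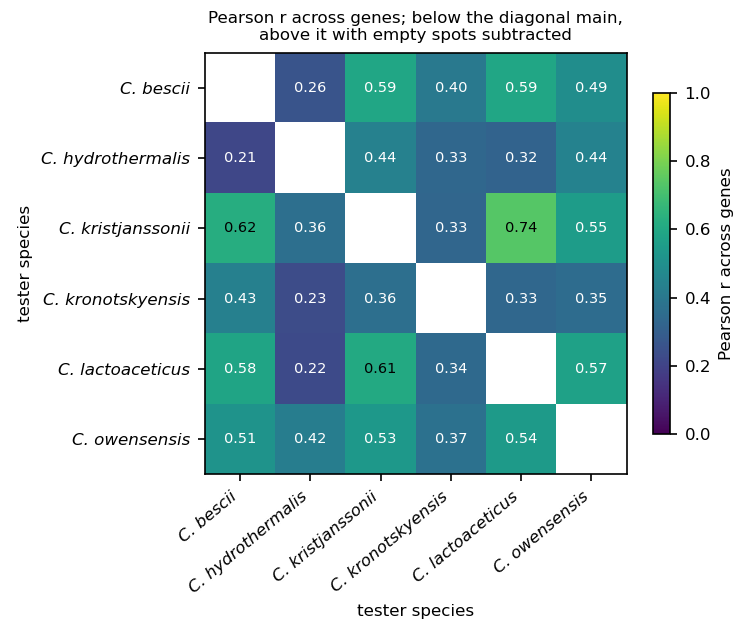
Pearson correlation across genes of log2 ratios between tester species; below the diagonal as reported, above it with the median of the empty spots subtracted. The pair of C. kristjanssonii and C. lactoaceticus has 0.61 below and 0.74 above the diagonal.

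Reduced genes lay in runs along the locus tags, whose order is taken here as gene order. Runs of 5 or more reduced genes, with gaps of 1 allowed, numbered 11 in C. kristjanssonii and 11 in C. owensensis, where 1000 shuffles of gene order gave at most 2 and 5. They held 64 genes in C. kristjanssonii (30.8% of its reduced genes) and 67 in C. owensensis (18.8%). C. bescii had 4 runs, against at most 2 in shuffles, but 0 with no gap allowed. C. hydrothermalis had 1, a number that shuffles also reached. C. lactoaceticus had 4, within the 7 that shuffles reached, but 18 with the empty spots subtracted, where shuffles reached 14. C. kronotskyensis had 0. With no gap allowed C. kristjanssonii and C. owensensis had 3 each, against at most 1 and 2 in shuffles, C. hydrothermalis 1 against 0, and C. lactoaceticus 1, within the 2 of shuffles. With the ratio turned, C. kristjanssonii would have 17 runs, C. lactoaceticus 11 and C. owensensis 20, against at most 10, 7 and 18 in shuffles, and they would hold 26.3%, 17.5% and 24.0% of those genes; C. kronotskyensis would have 1 against 0 in shuffles, C. bescii 0 and C. hydrothermalis 0. With 1 gene reduced in all 6 species, no run over all of them could be found. The longest run held 9 reduced genes in C. owensensis (Csac_1061 to Csac_1072), no more than the highest of the shuffles, and 8 in C. kristjanssonii (Csac_1382 to Csac_1391), against at most 7 in shuffles. The longest in C. hydrothermalis held 6, against at most 5, and that in C. bescii 8, which shuffles also reached.

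Several runs recurred. From Csac_1382 to Csac_1391, 8 of 10 genes were reduced in C. kristjanssonii, 7 in C. bescii, 7 in C. owensensis and 4 in C. lactoaceticus, with medians of -1.86, -2.23, -1.37 and -0.98, while none was reduced in C. kronotskyensis (median 0.54) and 2 of 9 were in C. hydrothermalis (-1.14). From Csac_2457 to Csac_2462, 5 of 6 genes were reduced in C. bescii, C. lactoaceticus and C. owensensis, with medians of -2.30, -1.75 and -2.33. There 3 of 6 were reduced in C. kristjanssonii (-1.39), 1 of 5 in C. kronotskyensis (-1.18) and 0 of 6 in C. hydrothermalis (-0.32). From Csac_1061 to Csac_1064, all 4 genes were reduced in C. hydrothermalis, C. kristjanssonii, C. lactoaceticus and C. owensensis, with medians of -1.96, -1.79, -2.16 and -2.05, and none in C. bescii (0.66) or C. kronotskyensis (0.71).

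**Figure D4:**
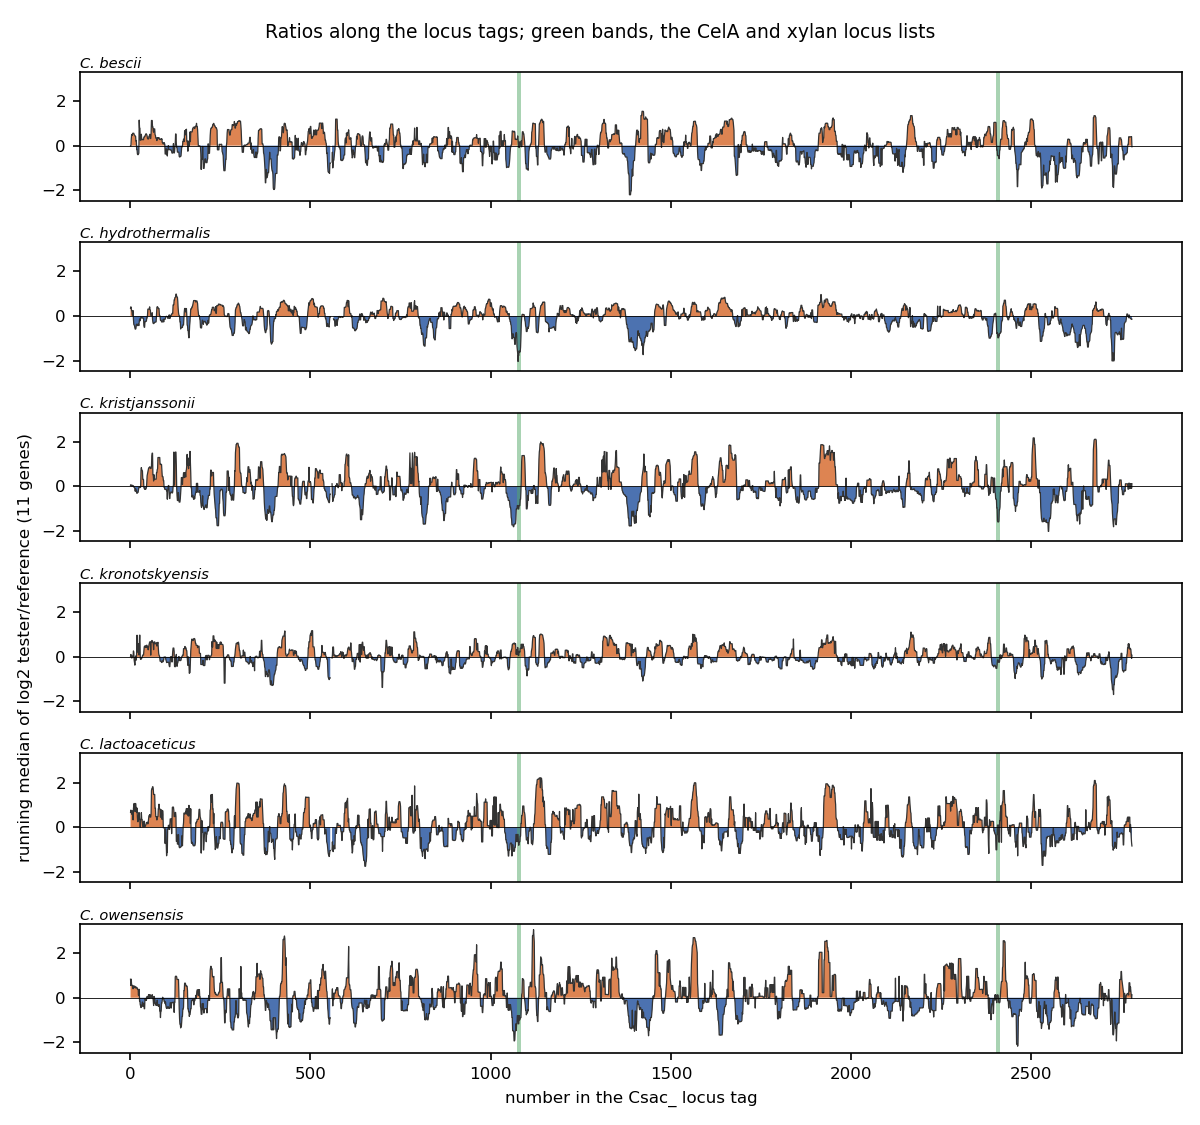
Running median over 11 genes of the log2 ratio of tester over reference along the numbers of the locus tags, for each tester species; blue is below 0, orange above 0, and green bands mark the CelA and xylan locus lists. A trough between Csac_1382 and Csac_1391 appears in C. bescii, C. kristjanssonii and C. owensensis and not in C. kronotskyensis, whose median there was 0.54. The medians there were below 0 in C. hydrothermalis (-1.14) and C. lactoaceticus (-0.98) too.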

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

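The tests on empty-spot subtraction, on a wrong dye name, on neighbours across arrays, on dye orientation between species and on genes in range were chosen after the result was seen; the others were set before it.

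Of 26 sets of values over the 6 species, 2 held a species far from the others, and chance alone would flag about 1 in 20. Csac_2406, in the xylan locus list, had a ratio of 3.20 in C. owensensis, against -1.54 to -0.52 in the other 5 species. Csac_2410, in the same list, had -0.59 in C. hydrothermalis, against 0.32 to 0.81 in the others.

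The array also held 98 probes outside the C. saccharolyticus gene set, which no comparison used. Their tester signal was above the 95th percentile of the empty spots on both arrays for 73 probes in C. bescii, 43 in C. hydrothermalis, 96 in C. kristjanssonii, 46 in C. kronotskyensis, 77 in C. lactoaceticus and 88 in C. owensensis. In the same order the reference signal was above that level for 95, 67, 98, 86, 98 and 98 of them, more than the tester in every species.

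In C. hydrothermalis the 2 orientations correlated at only 0.07 across genes. A wrong dye name on 1 array would give a negative correlation with the other species, but the lower of its arrays correlated at 0.18 with their mean. An absence of shared signal is argued against too: a gene on 1 array correlated at 0.22 with its neighbour in locus order on the other array, above the 0.0491 that 1000 shuffles reached at most, and above its correlation with itself. Uneven signal left after local background subtraction was examined by subtracting the empty spots. The orientations then correlated at 0.42, above the lowest of the other species under that subtraction (0.28 in C. kronotskyensis, which had 0.44 before it). That setting also raised the floor. On the Cy5 array of C. hydrothermalis the tester signal of empty spots had a median of 598 and a 95th percentile of 1220, beside a gene median of 883. Spots under the floor in both channels have a ratio of 0. The rise therefore cannot be told apart from an effect of the floor, and this explanation stays open. No biological explanation was tested, and dye bias of single probes was not tested for this species alone.

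Reduced genes clustered along the locus tags: the mean ratios of neighbours correlated at 0.37, where shuffles reached 0.0534. Print layout is argued against, since genes printed next to each other correlated at 0.0512. Shared brightness of the reference signal is argued against as well, since neighbours correlated at 0.43 after a trend on it was taken out. Gain or loss of blocks of neighbouring genes between species may account for the clusters; this is a hypothesis found and examined on the same data, and regional base composition was not tested.

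Reductions also fell on the same genes in several species, with 55 genes reduced in 4 or more. All of them (100%) had reference signal above the median gene, but independent lists within 20 bins of that signal give 5.26 such genes, which argues against brightness as the whole cause. Among 626 genes in range in C. bescii, C. kristjanssonii, C. lactoaceticus and C. owensensis, 35 were reduced in all 4, where independent lists give 1.53, which argues against the range of the arrays. Dye bias of single probes is argued against on the mean over species pairs only. Species correlated at 0.346 on arrays of opposite orientation and at 0.344 on arrays of the same orientation. Single pairs differed: C. hydrothermalis with C. kronotskyensis had 0.03 on opposite and 0.27 on the same orientation, and C. hydrothermalis with C. owensensis 0.36 and 0.25. A reduced call already needs both orientations, so for reduced genes this comparison adds little. Sequence specific to C. saccharolyticus may account for it, and so may a difference in the copy number of regions in the reference DNA, which was common to all species and was not tested.

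For the C. acetigenus-labelled pair, 3 of the 15 splits of 2 against 4 species, the real one included, gave at least the real 188 genes at an unadjusted p under 0.05. The others were C. lactoaceticus with C. owensensis, with 267 and 1 gene at limma's adjusted p under 0.05, and C. hydrothermalis with C. kronotskyensis, the highest with 328. C. hydrothermalis and C. kronotskyensis each lay alone in a range of array numbers, so the latter split joins separate ranges. With the range as a block, which leaves only the other 4 species to compare, the real split gave 137 such genes and none at limma's adjusted p under 0.05. The 15 splits are too few for a share under 0.05.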

How the results depend on the processing

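Empty-spot subtraction, detection against empty spots, blocks of neighbouring genes, the fit to 4 species, shuffles with no gap and all values with the ratio turned were chosen after seeing the data; the other settings were planned. Centring on ribosomal protein genes was not run, since no file names them. No paired analysis was possible because each species has 1 sample, so that the groups share fewer than 2 replicate numbers. Where a value below moved, the cause was not tested unless the setting itself (size, call rule, single array, fewer species) gives it.

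Counts of reduced genes moved over 1.5 times as follows. With normexp, C. hydrothermalis had 155 and C. kronotskyensis 115. In the same order, mean pixel signal gave 17 and 22, and subtraction of the empty spots, which also raised the floor, gave 30 and 30. Centring on the mode gave 130 in C. kristjanssonii, 211 in C. lactoaceticus and 210 in C. owensensis, and moved the median of all genes' means from 0.04 to 0.15. Loess gave 46 in C. hydrothermalis and 147 in C. lactoaceticus. The Cy3 array alone gave 423 in C. bescii, 293 in C. hydrothermalis, 542 in C. kristjanssonii, 104 in C. kronotskyensis and 638 in C. lactoaceticus, and the Cy5 array alone 528, 506, 406 and 344 in the first 4 of these. The authors' table gave 41 in C. hydrothermalis, 421 in C. kristjanssonii, 358 in C. kronotskyensis and 541 in C. owensensis; it holds 1 value per gene and species, so its calls also drop the rule on both orientations. In the order C. bescii, C. hydrothermalis, C. kristjanssonii, C. kronotskyensis, C. lactoaceticus and C. owensensis, a 1.5-fold size gave 516, 213, 446, 203, 679 and 627, and a 4-fold size 23, 3, 28, 5, 51 and 56. The mean of the orientations at -1, the nearer comparison for the authors' table, gave 453, 204, 396, 156, 575 and 484. Signal not above background, 0 in each species by local background, was 126, 30, 25, 215, 356 and 43 against empty spots.

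The count of genes reduced in all species, 1 as reported, was 3 with normexp, 0 without background subtraction, 0 with mean pixel signal, 0 with loess, 5 and 21 on the Cy3 and Cy5 arrays alone, 2 in the authors' table, 2 with empty spots subtracted, 6 at 1.5-fold, 0 at 4-fold, 10 with the mean of orientations and 45 in 4 species; leaving out 1 species gave 1 to 10 (10 without C. hydrothermalis, 5 without C. kronotskyensis, 2 without C. kristjanssonii or C. lactoaceticus). The count reduced in no species stayed within 1.5 times under every setting run. For the mean over species, 430 genes passed at any size on the Cy3 array alone, 312 were lower in 4 species, and leaving out 1 species gave 161 to 246 lower and 288 to 404 higher. With array-number range as a random block 163 were lower and 302 higher. For the pair, 3 genes passed with trend and robust eBayes and 0 under every other setting, the block included. Its profile correlation, 0.61, was 0.74 with loess, 0.43 on the Cy3 arrays and 0.74 with empty spots subtracted. The medians of both lists over the mean of 6 species stayed below 0 under every setting run, from -0.81 to -0.37 for CelA and from -0.91 to -0.29 for xylan. Single species moved further: the CelA median of C. hydrothermalis ran from -2.83 to -1.13 and that of C. owensensis from -2.28 to -0.80, and that of C. lactoaceticus turned above 0 with the filter on dim reference probes (0.26). The xylan median changed sign with the setting in C. kronotskyensis (-0.33 to 0.65), C. lactoaceticus (-0.89 to 0.42) and C. owensensis (-0.58 to 0.31). Among blocks of neighbouring genes the percentile of the mean over species was 5.41 for CelA and 12.7 for xylan, where scattered lists gave 0.44 and 0.47. Counting as a call limma's adjusted p under 0.05 at any size, the call for Csac_1081 was lost in 5 settings and that for Csac_2407 in 1 (-1.04 on the Cy3 arrays). Calls were gained for Csac_1076 without C. bescii (-1.53), Csac_1080 without C. bescii (-1.49) or C. kronotskyensis (-1.53), Csac_2406 without C. owensensis (-1.04) and Csac_2409 with normexp (-1.06) or loess (-0.81). The longest run was 4 in C. bescii with no gap, and with empty spots subtracted 2 in C. hydrothermalis, 17 in C. kristjanssonii, 2 in C. kronotskyensis and 18 in C. owensensis. Signal over empty spots limits the calls most in C. hydrothermalis and C. kronotskyensis, with 505 and 594 genes in range.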

Other observations

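All comparisons in this part were chosen after the results were seen. The region from Csac_1061 to Csac_1064 and the CelA locus list, which follows it in tag order, had their highest medians in C. bescii and C. kronotskyensis and medians below 0 in the other 4 species, except that the list turned above 0 in C. lactoaceticus among genes with reference signal on every array (0.26). From Csac_1068 to Csac_1072, between them, 4 of 5 genes were reduced in C. kristjanssonii and C. owensensis, 1 of 5 in C. lactoaceticus (median -0.90), 1 of 2 measured in C. hydrothermalis (-1.21), and none in C. bescii or C. kronotskyensis, whose medians were 0.28 and 0.32. The difference between these groups of species was not tested, since they were recognised from the values.

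With the median of the empty spots subtracted, runs of 5 or more reduced genes numbered 23 in C. owensensis, 19 in C. kristjanssonii, 18 in C. lactoaceticus and 6 in C. bescii, where shuffles of gene order reached 10, 4, 14 and 2. The longest held 18 reduced genes in C. owensensis (Csac_1425 to Csac_1447) and 17 in C. kristjanssonii (Csac_2722 to Csac_2741, median -2.48), above the 13 and 9 of shuffles, and 9 in C. lactoaceticus and 7 in C. bescii, within them. In C. hydrothermalis and C. kronotskyensis, under the higher floor of that setting, the longest then held 2.

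A run of 6 genes elevated in 4 or more species lay between Csac_1561 and Csac_1568, with a median mean ratio of 1.62. In 1000 shuffles the longest such run held 4. The same search among genes reduced in 4 or more species gave no run of 5 or more.

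The mean ratio correlated across genes with the brightness of the reference signal at -0.31, and at -0.06 with the empty spots subtracted.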
